A study of Rattus norvegicus with 13 samples.

How the data were processed

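DNA methylation was measured by methylated DNA immunoprecipitation and sequencing (MeDIP-seq) in 13 rat libraries, 6 from morula embryos and 7 from sperm. The labels give each library a tissue, a lineage (DDT or vehicle control) and a replicate number. Embryo libraries are labelled as pools of embryos, and no label states that any replicate comes from separate animals, so the p-values below measure the spread between these samples.

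The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR without versions, and the genome build Rnor_6.0. The 4 deposited tables hold raw read counts per 1000 bp window, 2782040 windows on 23 chromosomes including X, Y and MT. The authors also deposited RPKM values (reads scaled by window length and library total) in some of these tables, as well as an edgeR log2 fold change of the first named group over the second. Beside it stand the authors' edgeR p-value and its adjusted p-value per window, which are missing where the total of the compared libraries was under 60 or 70 counts. No label states whether duplicate reads were removed before counting. Counts shared between tables were identical in every window. The deposited RPKM values of a library were proportional to its counts, at 1.05 counts per read, so they add nothing to the counts, and 13 columns of them were not used here.

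Total counts ranged from 30386626 to 193750804 per library, and the median count per window from 5 to 49. Relative counts are given as CPM, counts per 1000000 counts of the library. The counting floor was set at 3 counts per library, which is 0.01548 CPM in the deepest library and 0.09873 CPM in the shallowest. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

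All tests below were run on the deposited counts with R 4.3.3 and edgeR 4.0.16 (quasi-likelihood test with the defaults of that version, TMM scaling, two-sided). Windows with a total of at least 5 counts per library of the comparison were tested. The test shares information on the spread between libraries over windows. For DDT against control in morulae the fit pooled it in full (infinite prior degrees of freedom). There a window's own spread did not enter its p. A window is said to pass the test at a Benjamini-Hochberg adjusted p under 0.05 over the tested windows. Effects are DDT over control, or morula over sperm, on the log2 scale, with a standard error taken from the size of the effect and its test. The 4 comparisons were DDT against control in morulae (3 against 3) and in sperm (4 against 3), and morula against sperm in the control lineage (3 against 3) and in the DDT lineage (3 against 4). An interaction term over all 13 libraries tested whether the DDT difference itself differed between morula and sperm. Neighbouring windows past the test in the same direction, at most 1 kb apart, were merged into regions.

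Further summaries were the number of windows changed in both lineages, the direction in morulae of the 1000 sperm windows of smallest p (against 1000 circular shifts of the window positions, and against windows matched on count), and the share of counts on X, Y and MT. These shares were compared by exact permutation tests, two-sided, with Benjamini-Hochberg adjustment over 12 tests. These choices, the tests above and most alternatives were fixed before the data were examined. Classes of windows by the sperm signal of the other lineage (10 classes), sums over 100 kb bins and all settings concerning the pair of sperm libraries that stand apart were chosen after seeing the data.

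Named windows followed a rule fixed beforehand for the case of no annotation: the 5 windows of smallest p per direction whose groups do not overlap, or, where none passed, the 3 of smallest p per direction, and the first 5 for the interaction. For a window whose control libraries are all at 0, the fold is a lower bound over 3 counts in the group. Where a group holds 1 to 3 counts in all, the ratio of pooled counts is given with its exact 95% counting interval.

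The alternatives were library-size scaling, DESeq2 size factors, DESeq2 1.42.0 as the test, edgeR with a trended dispersion, minimum totals of 1, of 10 and of 10 per library, thinning to the smallest library, leaving out the 0.1% of windows with the highest counts, a replicate block, leaving out each replicate, an unadjusted p under 1e-05, an added 2-fold minimum and the deposited p-values. An offset that removes the trend of counts with abundance in each library, and a term for the sperm libraries that stand apart, were added after seeing the data. The test was also tested on simulated data, in which 100 windows were changed 2-fold and 100 windows 4-fold. It recovered 2 and 46 of them in the design of the morula DDT comparison, 0 and 0 in that of the sperm DDT comparison, 0 and 10 in that of the control lineage, and 1 and 46 in that of the DDT lineage. False calls numbered 2, 0, 1 and 2 in these designs. Where far more windows change, as between morula and sperm, the cut-off on the adjusted p is less strict. These numbers therefore do not describe recovery in the morula against sperm comparisons.

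No gene annotation and no sequence of the build were used here, so promoters, gene lists and CpG density were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, limma 3.58.1 and matplotlib 3.10.9 served for the remaining steps.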

Results

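MeDIP-seq precipitates DNA fragments with an antibody against 5-methylcytosine, so the reads of a genomic window rise with its methylation and with the number of methylatable sites it holds. Gestating female rats of generation F0 received the insecticide DDT (dichlorodiphenyltrichloroethane) or the vehicle DMSO from embryonic day 8 to 14. Sperm came from males of generation F3, and morula embryos were made by injecting such sperm into eggs of donor females (ICSI). The groups were control morula (3 libraries), DDT morula (3), control sperm (3) and DDT sperm (4).

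The control morula libraries held 65864303, 58852592 and 48923904 counts, and the DDT morula libraries 37842198, 40787673 and 40051075. Control sperm replicates 1 to 3 held 144738902, 193750804 and 30386626 counts, and DDT sperm replicates 1 to 4 held 111944160, 104860839, 128386419 and 33684143. Control sperm replicate 3 and DDT sperm replicate 4 stood apart from the other 5 sperm libraries. As deposited they left 13.25% and 11.87% of windows without a count, against 4.97% to 6.35% in the other 11 libraries, and at equal depth 13.25% and 12.71%, against 8.86% to 11.24% in the other sperm libraries. At equal depth they placed 45.36% and 45.32% of counts in the top 10% of windows, against 33.86% to 36.66% in the other sperm libraries. Across windows, which are not independent replicates, log CPM correlated at r = 0.88 between these libraries, at 0.711 to 0.802 between them and the other 5, and at 0.883 to 0.946 among those 5. Morula libraries correlated at 0.675 to 0.771 with each other and at 0.485 to 0.629 with sperm.

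**Figure D1:**
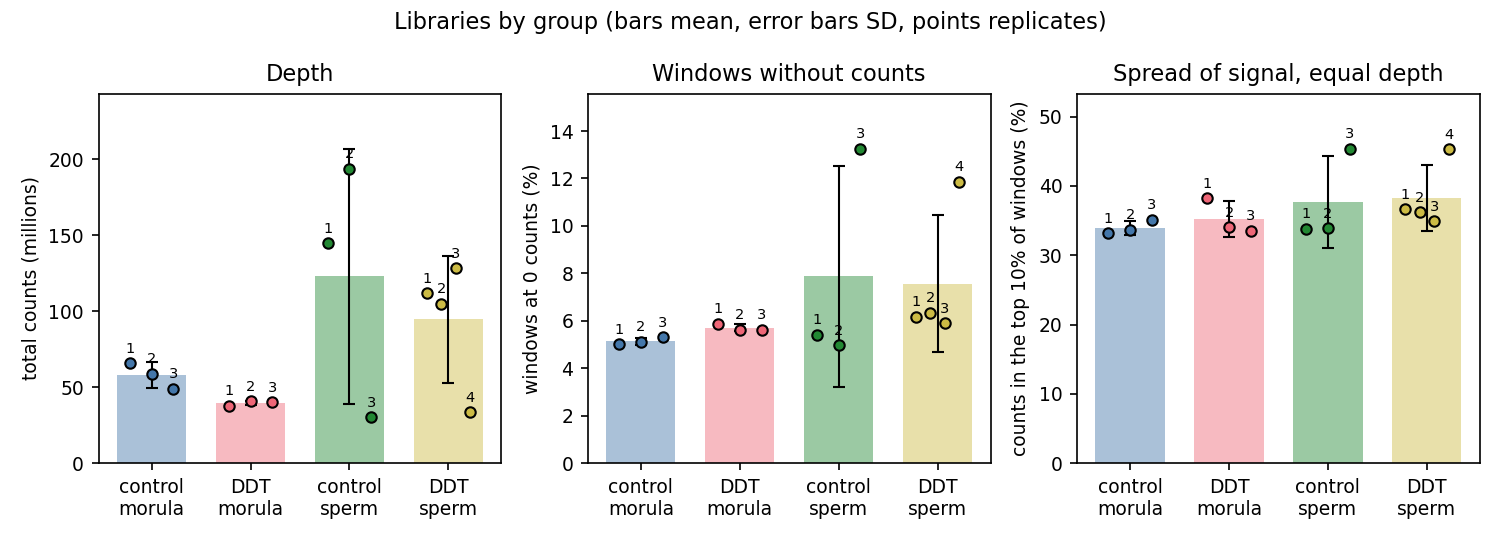
Total counts, windows at 0 counts (%) and, after thinning to equal depth, the percent of counts in the top 10% of windows, for the 13 libraries by group. Bars are means, error bars SD, points single libraries with their replicate number. Control sperm 3 and DDT sperm 4, the shallowest libraries, lie at 13.25% and 11.87% of windows without counts as deposited, and the others at 4.97% to 6.35%, while thinning to equal depth brings the other sperm libraries to 8.86% to 11.24%.

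The control lineage shows which regions differ in MeDIP signal between sperm and the embryo without ancestral exposure. The MeDIP signal differed over a large part of the genome: 435230 windows were higher and 318422 lower in morulae than in sperm, of 2582315 tested. Among the windows higher in morulae, the smallest p lay at the start of chromosome 8. Misplaced reads of mitochondrial DNA may account for the windows there and at 198590001 of chromosome 2, as described under other observations. The window at 182001 to 183000 of chromosome 8 had 6.59 ± 1.77 CPM (SD, n = 3) in morulae and 0.0616 ± 0.00455 CPM (n = 3) in sperm, a log2 difference of 6.67 (SE 0.48, adjusted p = 2.17e-05). Its neighbour at 181001 to 182000 had 11.3 ± 3.16 against 0.107 ± 0.015 CPM. Further windows past the test were at 198590001 to 198591000 of chromosome 2, with 3.29 ± 0.858 against 0.0552 ± 0.0223 CPM, and on chromosome 12 at 9545001 to 9546000, with 3.17 ± 0.566 against 0.0978 ± 0.0438 CPM, and at 9548001 to 9549000, with 1.08 ± 0.112 against 0.019 ± 0.0209 CPM. Among windows lower in morulae, the one at 138644001 to 138645000 of chromosome 7 fell from 1.45 ± 0.73 CPM in sperm to 0.0865 ± 0.0308 CPM in morulae (log2 difference -4.24, SE 0.48, adjusted p = 0.000166). The windows at 33756001 to 33757000 of chromosome 3, 9054001 to 9055000 of chromosome 5, 18567001 to 18568000 of chromosome 20 and 94589001 to 94590000 of chromosome 8 had log2 differences of -3.33, -3.23, -3.24 and -3.09. By the rule that chose these 10 windows, all 3 morula libraries lay on the same side of all 3 sperm libraries in each.

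Windows past the test in the control lineage merged into 234296 regions higher in morulae, of which 1498 held at least 10 such windows, and 172704 regions lower in morulae, of which 1112 did. The widest higher region covered 130 kb at 150342001 to 150472000 of the X chromosome, with a median log2 difference of 2.15 over its windows past the test. Regions of 120 kb at 96304001 to 96424000 of chromosome 3 and 113 kb at 10787001 to 10900000 of chromosome 8 followed, with medians of 1.96 and 1.97. The widest lower region covered 61 kb at 7204001 to 7265000 of chromosome 14 (median -1.5). The count depended on single libraries: it was 326316 without control morula replicate 1, 379379 without control morula replicate 2, 372618 without control morula replicate 3, 463467 and 447224 without control sperm replicate 1 or 2, and 1167407 without control sperm replicate 3. Thinning to equal depth left 229830 windows, and the abundance-trend offset 248842, of which 129712 were higher and 119130 lower. The balance of directions also depended on the setting, with 501560 higher and 270837 lower under library-size scaling, 234750 and 237613 by DESeq2, and 568498 and 598909 without control sperm replicate 3. DESeq2 passed 472363 windows in all, while the adjusted p deposited by the authors passes 569708, of which 524267 also pass here.

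The DDT lineage asks the same question in descendants of exposed females. In it 453318 windows were higher and 411410 lower in morulae than in sperm, of 2474205 tested. The balance of directions depended on scaling, with 517656 higher and 327887 lower by library size and 485852 and 348947 by DESeq2 size factors. On chromosome 20 the window at 19485001 to 19486000 had 9.38 ± 1.65 CPM (SD, n = 3) in morulae and 0.117 ± 0.0683 CPM (n = 4) in sperm, a log2 difference of 6.46 (SE 0.38, adjusted p = 3.93e-11). Its neighbour at 19484001 to 19485000 had 31.4 ± 4.36 against 0.677 ± 0.331 CPM. The neighbour's counts lay in the range where counts hardly rise with depth (1337, 1090 and 1290 in DDT morulae, 1123, 1378 and 1303 in control morulae). They were lowest in DDT morula replicate 2 and control morula replicate 1, as were the mitochondrial counts. Misplaced reads of mitochondrial DNA may account for both windows, as described under other observations, though the neighbour was not among the windows tested there. The windows at 181001 to 182000 of chromosome 8 and 198590001 to 198591000 of chromosome 2 were named in both lineages, here with log2 differences of 7.86 and 5.85. The fifth higher window was at 11964001 to 11965000 of chromosome 1, with 10.4 ± 0.641 against 0.341 ± 0.141 CPM. The windows of smallest p that fell in morulae were at 79948001 to 79949000 of chromosome 18, with 0.236 ± 0.064 CPM in morulae against 1.84 ± 0.36 in sperm (log2 difference -3.06, SE 0.38, adjusted p = 1.82e-06), at 55155001 to 55156000 and 101537001 to 101538000 of chromosome 10, at 115228001 to 115229000 of chromosome 8 and at 136981001 to 136982000 of chromosome 6, the last with 0.0831 ± 0.0509 against 1.15 ± 0.331 CPM. By the rule that chose these windows, all 3 morula libraries lay on the same side of all 4 sperm libraries in each.

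In the DDT lineage 249710 merged regions were higher and 212867 lower in morulae. The widest higher region covered 133 kb at 10767001 to 10900000 of chromosome 8 (median log2 difference 2.06), and the second 120 kb at 96304001 to 96424000 of chromosome 3, the same stretch as in the control lineage. Lower regions reached 58 kb, at 12033001 to 12091000 of chromosome 17 and at 7544001 to 7602000 of chromosome 20. The count was 542706 without DDT morula replicate 3 and 547714 without DDT morula replicate 2, while 508959 windows passed after thinning and 381220 with the abundance-trend offset (206481 higher, 174739 lower). The adjusted p deposited by the authors passes 523604 windows, of which 468243 also pass here.

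The lineages share no library, so windows changed in both show how far the difference between sperm and embryo was repeated. Of 2470110 windows tested in both, 255444 were higher in morulae in both lineages, where independent calls would give 66067, and 214166 were lower in both, against 52990. These independent numbers take every window as equally likely to pass. In the control lineage 70.5% of the lowest and 3.18% of the highest class of sperm signal passed as higher. The excess therefore includes what the lineages share through the level of signal, and does not by itself measure repetition window by window. In opposite directions 95 windows passed, with 964 without control sperm replicate 3, 356 without DDT sperm replicate 4 and 21 to 61 without any one of the other 11 libraries. Among nuclear windows with a mean of at least 100 counts in morulae, 7 were at least 16-fold higher there in both lineages, those named on chromosomes 2 and 8, at 9545001 of chromosome 12 and at 19485001 of chromosome 20 among them. Misplaced reads of mitochondrial DNA may account for 6 of these 7, all but that of chromosome 12, as described under other observations. The log2 differences correlated across windows at r = 0.824, and at 0.637 with the abundance-trend offset. The number shared was 469610 in all, with 129534 under that offset, 225006 without control morula replicate 1, 258128 and 252309 without control morula replicate 2 or 3, and 309574 and 311379 without control sperm replicate 1 or 2.

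The difference followed the level of signal in sperm. Morula and sperm libraries correlated at only 0.485 to 0.629, and with such a correlation classes formed by sperm signal can give this pattern by themselves. Classes by morula signal were not formed, so the choice of classes was not tested as a source. Windows were placed in 10 classes by the sperm signal of the other lineage, so that no library served both to form a class and to measure it. In the lowest class the control lineage rose from 0.0529 ± 0.013 CPM in sperm (SD, n = 3) to 0.207 ± 0.0053 CPM in morulae (n = 3), with a median log2 difference of 1.77, and 70.5% of windows passed the test as higher. In the highest class the median was -0.71, 35.1% of windows passed as lower and 3.18% as higher, and the class means of 1.24 ± 0.26 and 1.04 ± 0.024 CPM differed by less than the spread between sperm libraries. The DDT lineage went from a median of 1.79 in the lowest class to -1.06 in the highest, where 59.4% of windows passed as lower and 6.85% as higher. The median over the lowest class minus that over the highest shrank to 0.774 in the control and 1.11 in the DDT lineage with an offset that removes the trend of counts with abundance.

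**Figure D2:**
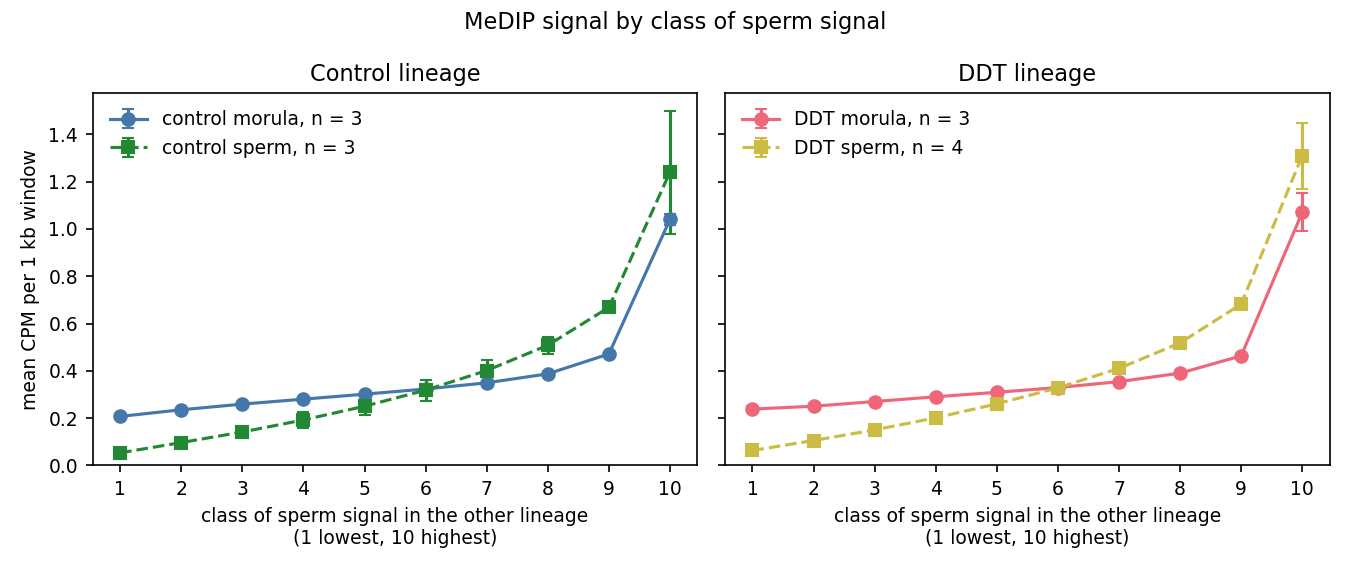
Mean CPM per 1 kb window (error bars SD between libraries) in morula and sperm, by class of sperm signal measured in the other lineage, for the control and the DDT lineage. In class 1 control morulae had 0.207 CPM and control sperm 0.0529, and from class 7 upward the sperm line lies above the morula line in both lineages.

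Chromosomes differed in direction. On chromosome 12, 23.8% of tested windows were lower and 12.2% higher in morulae in the control lineage, and 31.2% lower and 12.0% higher in the DDT lineage. Chromosome 20 had 19.8% lower and 13.5% higher in the control lineage and 24.8% lower and 14.8% higher in the DDT lineage, and chromosomes 10 and 19 leaned the same way. On X, by contrast, 17.3% of windows were higher and 2.63% lower in the control lineage, and 13.7% and 7.03% in the DDT lineage. Every library was precipitated, so signal and shares do not separate the methylation of a chromosome from its amount of DNA in the sample. Scaling by library size moved the median log2 difference over all windows from 0.087 to 0.18 in the control lineage and from -0.012 to 0.105 in the DDT lineage. With it chromosomes 12 and 20 still had more lower than higher windows in both lineages, while chromosome 19 in the control lineage had 16.0% higher and 15.7% lower. In the DDT lineage chromosomes 8 and 17 also turned, from 17.0% higher and 18.1% lower to 19.3% and 14.4%, and from 17.0% and 18.9% to 19.5% and 15.2%. The X chromosome carried 3.96% ± 0.11 (SD, n = 3) of counts in control morulae against 2.99% ± 0.41 (n = 3) in control sperm, and 4.03% ± 0.26 (n = 3) in DDT morulae against 3.16% ± 0.25 (n = 4) in DDT sperm. Y carried 0.149% ± 0.0027 against 0.119% ± 0.017 in the control lineage and 0.153% ± 0.0095 against 0.12% ± 0.0083 in the DDT lineage. All 17 windows of the mitochondrial genome were higher in morulae in both lineages, with its share at 0.0395% ± 0.0086 against 0.00301% ± 0.00035 in the control and 0.0559% ± 0.0061 against 0.00215% ± 0.0016 in the DDT lineage. Its counts in morulae did not rise with depth (19900, 24058 and 23138 in control and 23023, 20019 and 23121 in DDT morulae, median slope of log count on log depth -0.06), so its share there falls as depth rises. For X, Y and the mitochondrial genome alike, two-sided exact permutation tests gave p = 0.1 in the control lineage and p = 0.0286 in the DDT lineage, each the smallest its design allows, and adjusted p of 0.171 and 0.114 over 12 tests. Between DDT and control the exact p was 0.8, 0.7 and 0.1 in morulae for X, Y and the mitochondrial genome, and 0.514, 1.0 and 0.429 in sperm. The 0.1 for the mitochondrial genome in morulae is also the smallest its design allows (adjusted p = 0.171). Its share was higher in DDT morulae, whose libraries were the shallower ones.

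**Figure D3:**
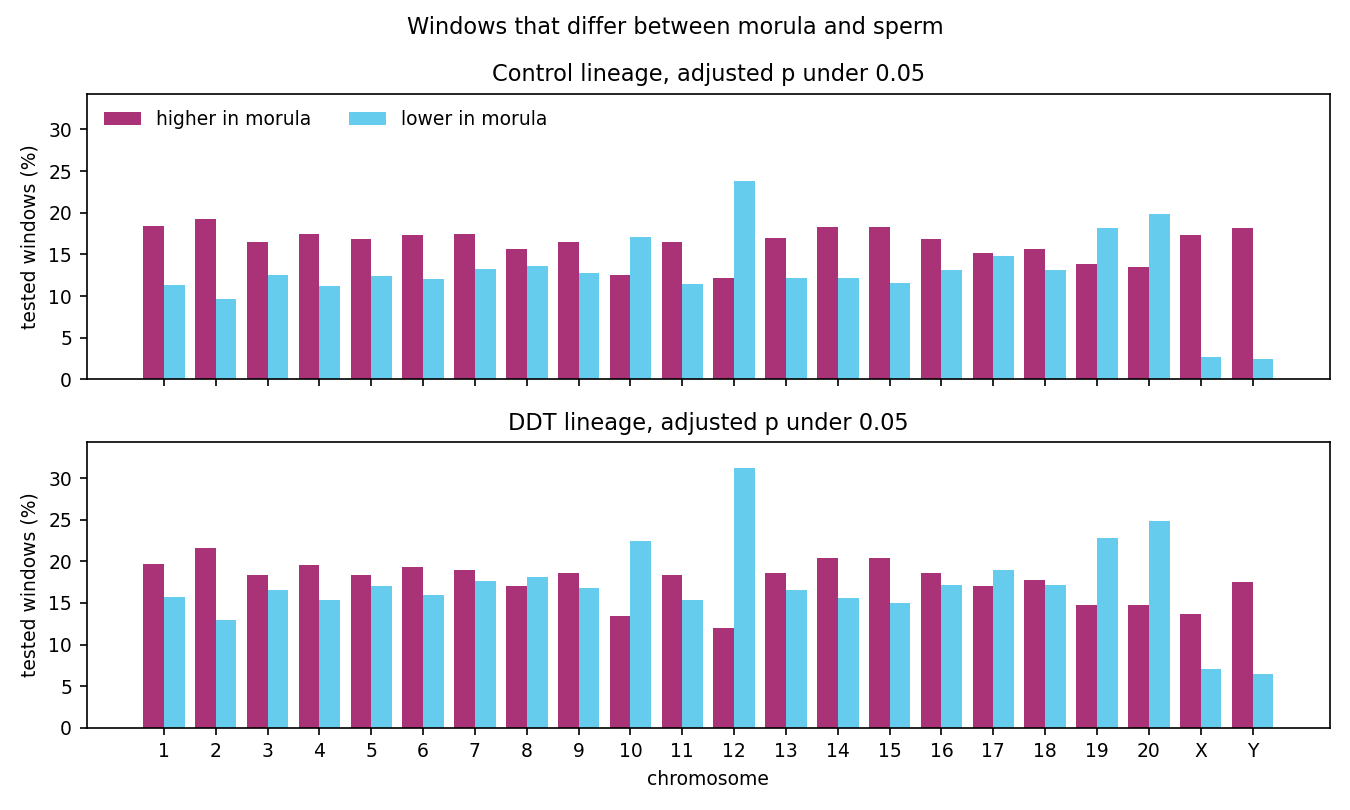
Percent of tested windows higher (purple) or lower (blue) in morula than in sperm per chromosome at an adjusted p under 0.05, in the control lineage (top) and the DDT lineage (bottom), with TMM scaling. Chromosome 12 has 23.8% and 31.2% of windows lower, and X 2.63% and 7.03%. Under scaling by library size chromosome 19 of the control lineage turns, with 16.0% higher and 15.7% lower, as do chromosomes 8 (19.3% and 14.4%) and 17 (19.5% and 15.2%) of the DDT lineage.

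Sums over 100 kb bins balanced directions differently from windows. In the control lineage 9208 bins were higher and 9308 lower in morulae, of 27777, and in the DDT lineage 10975 and 10419. Most were small: 282 higher and 77 lower bins of the control lineage, and 287 and 60 of the DDT lineage, reached 2-fold. The bin at 149900001 to 150000000 of X had log2 differences of 2.34 (SE 0.14) in the control and 2.29 (SE 0.17) in the DDT lineage. That at 115200001 to 115300000 of chromosome 2 had 2.29 and 2.08, and that at 21700001 to 21800000 of chromosome 9 had 2.06 and 2.03. Lower in both were the bins at 37900001 to 38000000 of chromosome 9, with -1.39 and -1.21, and at 103800001 to 103900000 of chromosome 15, with -1.23 and -1.15. The bins' differences correlated at r = 0.976 between lineages, 8708 were higher and 9046 lower in both, and 0 were opposite, with both tests by edgeR.

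In sperm the question is which regions differ between the DDT and the control lineage in generation F3. With all 7 libraries edgeR passed 0 of 2454365 windows, with 145414 at an unadjusted p under 0.05, while edgeR with a trended dispersion passed 0 and DESeq2 passed 15 higher and 4 lower. The higher windows of smallest p, none past the test (adjusted p = 0.843 by edgeR), had counts in DDT sperm where control sperm had few or none. At 60962001 to 60963000 of chromosome 3, all 3 control libraries had 0 counts and DDT replicates 1 to 4 had 84, 75, 93 and 2, at least 69-fold higher. The adjoining window at 60963001 to 60964000 had 3 counts in control and 192 in DDT sperm, a pooled ratio of 62.3 (95% counting interval 21 to 305). DDT replicates 1 to 4 had 55, 55, 81 and 1 of these counts, replicate 4 being below the counting floor. At 113596001 to 113597000 of chromosome 7 control sperm had 0 counts and DDT sperm 20 to 31 per library, at least 40-fold higher. Lower in DDT sperm, and not past the test, were windows of chromosome 6 at 52199001 to 52200000, with 96 counts in control and 1 in DDT sperm (pooled ratio 98.6, interval 17.3 to 3930), and at 52203001 to 52204000, with 137 and 11 counts, and the window at 5265001 to 5266000 of chromosome 14, with 140 and 8.

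The sperm count rested on control sperm replicate 3 and DDT sperm replicate 4, the libraries of low depth that stand apart. Without control sperm replicate 3, 2 windows passed as higher and 15 as lower, and without DDT sperm replicate 4, 2 as higher. Without both, a setting chosen after seeing the data, 160904 windows were higher and 100986 lower in DDT sperm, of 2513536 tested, and with a term for both libraries 128803 and 78436. In the 5 remaining libraries the split between directions depended on scaling, with 129782 higher and 132766 lower by library size. All 6 named windows passed in both of these settings, the one at 60962001 of chromosome 3 with an adjusted p of 7.38e-19 without both libraries. Over its alternatives that p ranged up to 1.0. The adjusted p deposited by the authors passes 28 windows, 14 higher and 14 lower.

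In morulae the question is whether a DDT lineage difference is present in the embryo. Of 2568322 windows 1 passed, lower in DDT morulae, at 77263001 to 77264000 of X, with 84, 8 and 4 counts in control morulae and 0, 2 and 3 in DDT morulae (0.498 ± 0.674 against 0.0413 ± 0.038 CPM, log2 difference -3.59, SE 0.58, adjusted p = 0.00194). It was below the count minimum without control morula replicate 1, which holds most of its counts, and had an adjusted p of 0.24 without DDT morula replicate 2. Because the fit pooled the spread over windows, the spread of this window's control counts (84, 8 and 4) did not enter its p. The higher windows of smallest p did not pass: 105196001 to 105197000 of X had 2 counts in control and 36 in DDT morulae (pooled ratio 26.3, interval 6.78 to 226, adjusted p = 0.064), 84244001 to 84245000 of chromosome 10 had 0.094 ± 0.03 against 0.485 ± 0.147 CPM (adjusted p = 0.313), and 225171001 to 225172000 of chromosome 2 had 0.23 ± 0.0368 against 0.731 ± 0.0839 CPM (adjusted p = 0.539). By edgeR 0 windows passed as higher, with 125758 windows of either direction at an unadjusted p under 0.05, and DESeq2 and edgeR with a trended dispersion passed 0 in either direction. Leaving out DDT morula replicate 1 gave 39 higher and 3 lower windows. The adjusted p deposited by the authors passes 2 windows, both higher, neither past the test here.

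Over 100 kb bins, 2 passed in morulae, both higher in DDT. The bin at 180600001 to 180700000 of chromosome 1 had 137 ± 5.61 CPM (SD, n = 3) against 104 ± 13.6 (n = 3), a log2 difference of 0.41 (SE 0.07, adjusted p = 0.0429 by edgeR). That at 40900001 to 41000000 of chromosome 20 had 30.5 ± 0.401 against 24.2 ± 2.37 CPM (0.35, SE 0.06, adjusted p = 0.0373). In these bins 6 windows and 1 window with a mean of at least 200 counts held 84.2% and 84.3% of the morula counts. The counts of those windows rose with depth at slopes of only 0.16 and 0.3, and the DDT morula libraries were the shallower ones. Without them the log2 ratios of mean CPM were 0.12 and 0.07, against 0.39 and 0.33 with them. The count of bins was 6 without DDT morula replicate 1, and 0 without control morula replicate 1 or 2 or DDT morula replicate 2 or 3. In sperm edgeR passed 0 of 27777 bins, with 926 at an unadjusted p under 0.05, and no other tool was run for bins. It passed 1 without DDT sperm replicate 4 and 4176 without both libraries that stand apart.

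Sperm windows were followed into the embryo to see whether their direction carried over. Of the 1000 sperm windows of smallest p, none past the test, 53.1% had the same direction in morulae, with a median morula log2 difference of 0.04 in the direction of sperm. Circular shifts of the positions gave a median of 49.9% and a 95th percentile of 52.6% (one-sided permutation p = 0.025). Shifts take windows as the units, so this p does not measure the spread between libraries. The share fell to 47.6% without DDT morula replicate 1, 49.9% without control sperm replicate 1, and 48.9% and 49.7% without DDT sperm replicate 1 or 2, each with a morula median in the opposite direction to sperm. Without control morula replicate 1, control sperm replicate 2 or DDT sperm replicate 3 the one-sided permutation p was 0.19, 0.4 and 0.27. The share was 64.6% when the 1000 windows were taken without both sperm libraries that stand apart, a setting chosen after seeing the data. No morula library was left out in that setting. Over all windows called in it, single pairs of a DDT and a control morula library went the same way as sperm in 53.1% to 53.9% with DDT morula replicate 1. Pairs with DDT morula replicate 2 or 3 did so in 49.6% to 50.6%.

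The interaction tested whether the DDT difference itself differed between morula and sperm. No window passed in edgeR, 0 of 2551260, with 144809 at an unadjusted p under 0.05, and no other tool was run for it. All groups share one estimate of the spread in this test, though the common dispersion was 0.00673 in the morula and 0.0642 in the sperm DDT comparison. Recovery by the interaction test was not simulated, so 0 windows does not show that the effects were alike. The windows of smallest p (adjusted p = 0.869 for each) included 64930001 to 64931000 of chromosome 16, with 0.315 ± 0.273 CPM in control and 0.0214 ± 0.0165 in DDT sperm but 0.884 ± 0.228 and 0.968 ± 0.0319 in morulae. At 23231001 to 23232000 of chromosome 14 control and DDT sperm had 0.0512 ± 0.0486 and 0.24 ± 0.0904 CPM, and control and DDT morulae 0.376 ± 0.0121 and 0.151 ± 0.0216. The others were at 37703001 to 37704000 of chromosome 16, at 60964001 to 60965000 of chromosome 3 and at 52199001 to 52200000 of chromosome 6, the last also among the sperm windows above. Without control sperm replicate 3, 8 windows passed with a higher and 3 with a lower difference in morulae, without control sperm replicate 2 there was 1, and a term for the libraries that stand apart gave 895 and 3835.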

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

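The tests on the 5 sperm libraries that remain without the pair that stands apart, their splits included, were chosen after the result was seen. DDT sperm replicate 4 lay far from the other 3 DDT sperm libraries in several measures. It left 11.9% of windows without counts as deposited (others 5.89% to 6.35%) and, not flagged, 12.71% at equal depth (others 10.54% to 11.24%). It placed 45.3% of its counts in the top 10% of windows as deposited (others 34.1% to 35.9%) and 45.3% at equal depth (others 34.9% to 36.7%). Its level was 0.0594 CPM at 60962001 to 60963000 of chromosome 3 (others 0.715 to 0.75) and 0.208 CPM at 198590001 to 198591000 of chromosome 2 (others 0.0477 to 0.0715). At 52199001 to 52200000 of chromosome 6, DDT sperm replicate 1 had 0.00893 CPM, which is 1 count, and the other DDT sperm libraries had 0. In all 25 groups of 4 samples were examined and 6 held such a sample, where chance gives about 1 in 20 for independent groups. These groups share libraries and measures, so that rate does not apply to their number. Groups of 3 were not tested in this way. In the interaction test of edgeR 0 windows passed, with 144809 at an unadjusted p under 0.05, which does not show that the DDT effect was alike in both tissues.

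Without both libraries that stand apart, 261890 windows differed between lineages in the remaining 5 sperm libraries. Against a difference in depth or spread of signal among these 5 as the whole cause, 193876 windows passed after thinning to equal depth and removing the trend with abundance. In the ratio of DDT sperm replicate 4 to control sperm replicate 3, which took no part in that test, 58.7% of 220689 called windows with at least 10 counts went the same way, with a median log2 ratio of 0.11 against 0.78 in the 5. This sets 1 library against 1 with no sperm pair of one lineage outside that test to give its spread, and in morulae, where 53.0% of 260582 windows did so, pairs of the same lineage already lay up to 3.39 points from 50%, so neither decides. A lineage difference, a sperm batch that coincides with lineage and a broad property such as CpG density (not analysed here) that moves both pairs of groups stay open, and the splits are too few for a share under 0.05 (1 of the 10 splits of the 5 libraries as large, real count 51095, highest other 6, on every 5th window).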

How the results depend on the processing

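The abundance-trend offset, the term for the sperm libraries that stand apart, their removal, and every setting of the bins and of the classes of sperm signal were chosen after seeing the data. Direction and side of the threshold held in 328 of 353 alternatives of the named windows, 2 ended a call, 23 gained one and 0 reversed. This tally covers alternatives with a fit per window: the X window at 77263001 also had no call with DESeq2 or a trended dispersion and fell below the count minimum without control morula replicate 1. The 10 named windows of each morula against sperm comparison kept their call in the 109 (control lineage) and 118 (DDT lineage) alternatives run for them. They were chosen for the smallest p in the same data, so this says little about the other windows. Thinning, DESeq2 and a trended dispersion were not among these alternatives. In morulae DDT against control gave 81 windows with the offset, 33 at an unadjusted p under 1e-05, 2 by the deposited p, and 0 with DESeq2, with a trended dispersion and with a replicate block (numbers that the counts did not pair), 0 to 42 with a library left out and 0 to 6 bins. In sperm it gave 207239 with the term, 261890 without both libraries, 19 with DESeq2, 13 at 1e-05, 28 by the deposited p and 0 to 17 with a library left out. Sperm bins gave 1969, 4176 and 0 to 1. The control lineage gave 229830 thinned, 248842 with the offset, 472363 with DESeq2, 30124 at 1e-05 and 326316 to 1167407 with a library left out, and 13645 to 24229 bins. The DDT lineage gave 519321 at 10 counts per library, 508959 thinned, 381220 with the offset, 81759 at 1e-05, 523604 by the deposited p, 542706 to 1105530 with a library left out and 19187 to 24153 bins. Windows changed in both lineages numbered 14704 at 1e-05, 129534 with the offset and 225006 to 600789 with a library left out. The interaction gave 4730 with the term, 8 at 1e-05 and 0 to 11 with a library left out. The share of sperm windows with the same direction in morulae ranged from 47.6% to 57.6% with a library left out, reversed at 47.6%, 49.9%, 48.9% and 49.7%, and was 63.2% with the term, 64.6% without both libraries and 87.5% of the 8 windows at 1e-05.

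Without the 0.1% of windows with the highest counts, which takes out most mitochondrial windows, the differences in mitochondrial share were 0.000359 (morula DDT minus control), 0.00073 (control lineage) and 0.00111 points (DDT lineage). The lowest minus the highest class of sperm signal was 2.55 and 3.25 at a total of 10 counts, 2.08 and 2.47 thinned, 0.774 and 1.11 with the offset, which removes trends with abundance by construction, and 2.23 to 2.79 and 2.67 to 3.03 with a library left out. Fewer counts per library were tested on thinning, and fewer windows at 10 per library. For the other changes the cause was not tested. In the sperm DDT comparison 0 of 100 simulated 4-fold changes were recovered, so a change of that size in few windows was not detectable at its depth and spread. The CpG-density offset, alone and with the replicate block, all promoter, gene-list and CpG-density results, and their alternatives were not run, since no annotation or sequence of the build was used here.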

Other observations

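Of the tests in this part, those on the classes of sperm signal and both on the window of chromosome 12 were chosen after the result was seen. So was the comparison of raw morula counts with deeper sperm libraries in the other windows. With the abundance-trend offset 81 windows passed in morulae, 75 higher and 6 lower in DDT than in control. Of the 75, 69 had a mean count of at least 200, 17 of them mitochondrial and 52 nuclear. Among nuclear windows of morulae with a mean of 10 to 20 counts, the log count rose with log depth at a median slope of 1.09, among those of 1000 to 2000 counts at 0.28, and for the mitochondrial windows at -0.06. The highest count of any window in any library was 2000, the number of strand positions of a window, and where counts are flat CPM falls as depth rises (the DDT morula libraries were the shallower ones). No label states whether duplicate reads were removed before counting, which could flatten counts in this way and stays open, and with it what the CPM, folds and shares of such windows measure.

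In both lineages 7 nuclear windows on 5 chromosomes with a mean of at least 100 counts in morulae were at least 16-fold higher there than in sperm. Over the 6 morula libraries their counts had a median r of -0.21 with depth (-0.42 to -0.07 in 6 windows). The window at 9545001 to 9546000 of chromosome 12 followed depth there at 0.83. Flat counts raise CPM in shallower libraries, so this r does not decide on depth. Against depth as the cause, the lowest morula count of each window exceeded its highest in the 5 sperm libraries deeper than every morula library. These counts were 516 against 19 at 181001 of chromosome 8, and 114 against 28 (4.07 times) in the window of chromosome 12. Reads of mitochondrial DNA placed on nuclear copies of it may account for 6 of the 7 windows, since the median r with mitochondrial counts was 0.91 and 700 windows matched on count had a 95th percentile of 0.19. For the window of chromosome 12 that r was -0.29, which argues against this source there. The mitochondrial counts fall into separate groups (19900 and 20019 in control morula replicate 1 and DDT morula replicate 2, 23023 to 24058 in the other 4), so a high r shows only that a window shares the low pair, and another source shared by that pair and a true difference of the embryo at these loci stay open, untested.

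Windows of low sperm signal were higher and those of high sperm signal lower in morulae. Against depth as the whole cause, the log2 ratio of the lowest class minus that of the highest was 2.93 and 2.66 against control sperm replicate 3 and DDT sperm replicate 4, which were shallower than every morula library of their lineage, and 1.7 to 2.25 against the deeper sperm libraries. The medians of the fits lay 2.08 and 2.47 apart after thinning to equal depth, and 0.774 and 1.11 with the abundance offset. Evenly spread background reads in the morula libraries are argued against as the whole cause, since a share fitted to the lowest class (46.0% and 51.3% of reads) missed the level of another class by up to -21.0%. The choice of classes by sperm signal alone, a background that is not even and a difference in CpG density (not analysed here) stay open. So does the difference in methylation between sperm and embryo that the design names, and these may act together.

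Other splits of the same libraries were tested for each comparison. For DDT against control in morulae 8 of the 10 splits gave as many windows (real 1, highest other 2), so most other groupings called as many as lineage. For the control lineage 1 of the 10 splits did (real 753652, highest other 0). In both comparisons 10 splits are too few for a share under 0.05. For DDT against control in sperm 35 of the 35 splits gave as many, on every 5th window (real 0, highest other 22621). With a real count of 0 every split gives as many, so this count of splits says nothing about chance. That highest split set control sperm replicate 3 and DDT sperm replicates 1 and 4 against the rest and points to a structure of the samples other than lineage. In the DDT lineage 1 of the 35 splits was as large on every 5th window (real 172789). That share is under 0.05 but is the smallest this design allows. The highest other, 72168, set DDT sperm replicate 4 with the morulae. For the interaction 100 of the 100 relabellings on every 50th window gave as many (real 0, highest other 3), which for the same reason says nothing about chance.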
